A study of Homo sapiens with 6 samples.

How the data were processed

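The study used MDA-MB-231, an established human cell line of triple-negative breast cancer. RNA was extracted with Trizol and made into libraries with a YEASEN MaxUp Dual-mode mRNA kit, per the labels' protocols. The series compared control cells with cells given colistimethate, the prodrug of the polymyxin antibiotic colistin, at 20 µM in 3 repeats. The 6 libraries are titled C1 to C3 and K1 to K3. The labels do not say which letter is the treated arm, so every comparison is given as C against K, and no library is called treated or control. Whether the 3 libraries of a letter came from separate cultures is not stated beyond the word for repeats, so p-values measure the spread between these libraries, which may be partly technical.

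The authors deposited 1 table with 3 values per gene and library. The columns headed as counts held whole numbers and were taken as reads per gene, not normalised. TPM and FPKM, which scale by gene length and library total, were also deposited by the authors, per the file headers. The submitters' processing notes name FastQC 0.11.2, Trimmomatic, HISAT2 2.1.0 and StringTie 1.3.3b with the builds GRCh38 and hg38. Which tool made the counts and whether counting used strand are not given in the sources used here. Gene positions are printed as the deposited table gives them, on GRCh38.

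The table used here held 13707 complete genes and 1 further row that stopped after its gene ID. TPM of the listed genes summed to between 67.1% and 67.9% of the full TPM total per library, so part of the genes was not analysed here. ABI2, which the series title names, was among those not analysed here. Library totals are therefore sums over the listed genes. They were 33126624, 33339068 and 32637531 reads for C1, C2 and C3, and 31438065, 35946691 and 31552549 reads for K1, K2 and K3. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was at least 22.4 for every pair.

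The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 9057 genes. Libraries were scaled by TMM, with factors between 0.993 and 1.007. The quasi-likelihood test compared C with K on the 6 libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A second count also asked for a 2-fold change. Log2 fold changes are C minus K, and their standard error (SE) is the size of the change divided by the square root of the F statistic. The common biological coefficient of variation was 13.2%. Levels are given as CPM (counts scaled to the library total) with the SD over 3 libraries.

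The same steps were tested on simulated counts for 8988 genes with 50 genes changed at each fold size. They recovered 24% of genes changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 98% at 3-fold, and 9 of 165 calls were false. Most changes of 1.25-fold were thus not called in the simulation. The changed genes were drawn only from those at or above the median average expression, so recovery at lower expression was not measured.

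Before the data were examined, 33 gene lists were fixed, covering signalling, stress, metabolism, cell cycle, other cell types and RNA quality. Each list with at least 5 tested members was tested with camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over lists. Each was also tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance. Counts of members are given over all genes tested and adjusted over the list alone.

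Genes named in the text followed a rule fixed at the same time. It took the 8 largest rises and 8 largest falls among genes past the threshold, with average expression at or above the median of tested genes and no overlap between C and K libraries. It added up to 3 members past the threshold, by smallest p, of each called list, up to 1 of each other list, and the most abundant member of each list for another cell type or RNA quality. The rule gave 51 genes. Other genes named are said to have been chosen after their values were seen.

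Alternatives fixed beforehand were a replicate block, DESeq2 size factors, library size only, no filter beyond 1 read, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), and leaving out each library in turn. Leaving out mitochondrial-genome genes, and an offset for GC content and gene length, were added after the data were seen. Shared sequence was measured against GENCODE release 29 as the percent of a gene's 75-base exonic windows found in another gene. Exon overlaps came from the same annotation. Genes with shared windows or same-strand overlaps are uncertain where counting could split reads, and antisense overlaps are uncertain because the use of strand is not stated.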

Results

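Messenger RNA was sequenced from MDA-MB-231 cells, a triple-negative breast cancer line, in 3 libraries titled C and 3 titled K. The series asks how gene expression differs between control cells and cells given the antibiotic prodrug colistimethate at 20 µM, and its title names PI3K/Akt signalling. Because no label ties a letter to an arm, each difference below is C relative to K. Depth over the listed genes was 33034408 ± 359745 reads in C and 32979102 ± 2570645 reads in K (SD, n = 3 each), with a range from 31438065 to 35946691 reads.

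Transcripts of the mitochondrial genome (11 of 11 tested) and interferon-stimulated genes (12 of 22) were lower in C, while 6 of 15 genes in a list of endoplasmic reticulum chaperones and the unfolded protein response were higher. In a list of the ATF4 stress response and amino acid supply, 5 of 25 were higher and 1 was lower. These 4 lists passed camera with its preset correlation. None did with an estimated correlation, with adjusted p of 0.219, 0.0538, 0.119 and 0.119 in that order. The estimated correlations were 0.564, -0.034, -0.0107 and 0.011 in the same order, against the preset 0.01. Those after the mitochondrial list lay near or below the preset, so correlated members do not explain these lost calls. Of 9057 genes tested, 508 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 199 higher and 309 lower in C. Most changes were small. The 26 genes that also changed at least 2-fold all lay below the median average expression of tested genes (5.43 log2 CPM), the highest at 5.13. Of these 26, 2 were higher and 24 lower in C. That split was not stable, with 7 higher and 6 lower without K1, and the count was 9 without C1, 15 without C2, 14 without C3, 16 without K3 and 26 without K2. Among genes at or above the median expression, the largest fall by the naming rule was IFIT1, an antiviral protein encoded at chromosome 10, 89392546 to 89406486 on GRCh38, at 55.8 ± 2.49 CPM in C against 107 ± 4.30 CPM in K (log2 fold change -0.94, SE 0.050, adjusted p = 0.00145). The complement component C3 (chromosome 19, 6677704 to 6730562) was at 234 ± 11.4 CPM in C against 423 ± 9.99 CPM in K (log2 fold change -0.86, SE 0.044, adjusted p = 0.00144). The largest rise among the same genes was HLA-C, which presents peptides to T cells, with a log2 fold change of 0.80 (SE 0.15, adjusted p = 0.0404), although C1 was at 139 CPM and C2 and C3 at 204 and 210 CPM. HLA-C belongs to a multigene family, though it shares 1.3% of its 75-base windows with other genes in the reference, and its call was lost when any library except C1 was left out, with adjusted p between 0.0689 and 0.120. The first principal component, with 28.5% of the variance, placed every C library on one side and every K library on the other. The second, with 20.9%, did not separate the letters. The count of called genes fell to 77 without C1, 116 without C2, 109 without C3, 117 without K1 and 99 without K3. Without K2 it was 533, of which 326 were among the main 508. DESeq2 called 1039 genes, 526 higher and 513 lower in C, so the share lower in C was 49.4% against 60.8% in edgeR.

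**Figure D1:**
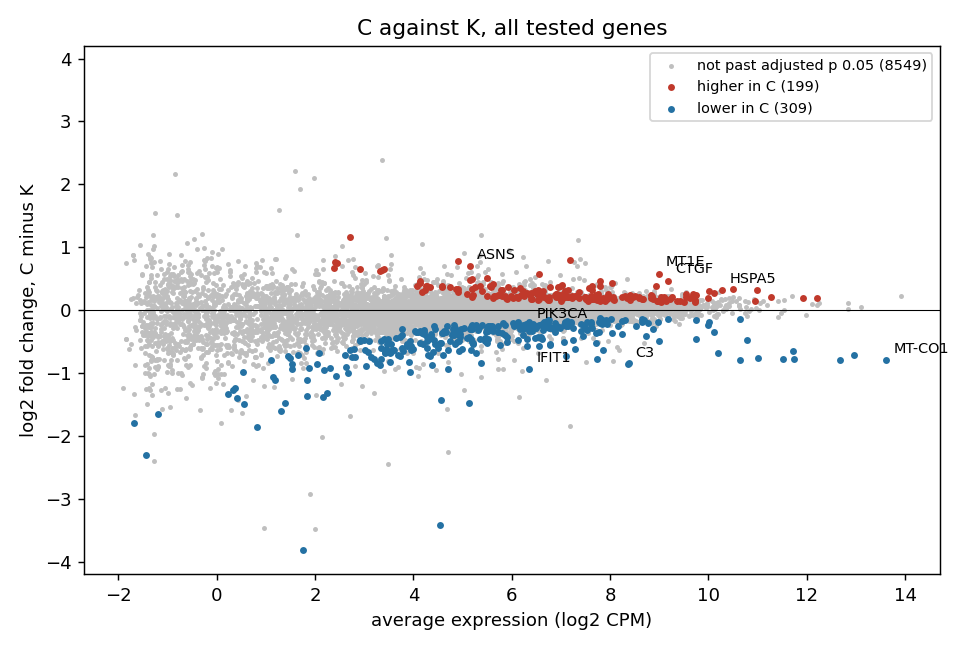
Log2 fold change of C minus K against average expression in log2 CPM for 9057 tested genes, with genes past an adjusted p of 0.05 in red (199 higher in C) and blue (309 lower in C). Most called genes lie within 1 log2 unit of 0, and 4 genes lie outside the axis range of 4.2 log2 units.

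The mitochondrial genome encodes subunits of the respiratory chain and ATP synthase. All 11 of its tested transcripts fell in C, with a median log2 fold change of -0.78, and 11 also passed when adjusted over the list alone. MT-CO1, a subunit of cytochrome c oxidase, was at 9135 ± 186 CPM in C and 15917 ± 1285 CPM in K (log2 fold change -0.80, SE 0.059, adjusted p = 0.00225). MT-ND6 (log2 fold change -0.85, adjusted p = 0.00171), MT-ND4 (-0.80, adjusted p = 0.00281), MT-ND4L (-0.79, adjusted p = 0.00500), MT-ND5 (-0.79, adjusted p = 0.00287) and MT-CYB (-0.78, adjusted p = 0.00277) fell by similar amounts, as did MT-ATP6 (-0.68, adjusted p = 0.00165). MT-ND3, named after its values were seen, fell least (-0.34, SE 0.064, adjusted p = 0.0389). MT-CO1 lies at chromosome MT, 5904 to 7445, and shares 36.6% of its 75-base windows with nuclear copies, while MT-CYB (MT, 14747 to 15887) shares 0.0%. As a share of listed reads, these transcripts took 3.21 ± 0.0806% in C and 5.41 ± 0.429% in K (SD, n = 3). The list passed camera with an adjusted p of 1.87e-12, and had an adjusted p of 0.219 with an estimated correlation. That correlation was 0.564 against the preset 0.01, so the 11 transcripts did not vary independently. Nuclear genes for oxidative phosphorylation did not pass as a list (median 0.05, adjusted p = 0.126), and 0 of 41 tested members passed.

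Interferon-stimulated genes, which cells induce against viruses, were lower in C. Of 22 tested members, 12 fell and 0 rose, with a median log2 fold change of -0.67 (-0.39 with limma on log2(TPM + 1)). Adjusted over the list alone, 15 fell. IFIT3, a related antiviral protein encoded at chromosome 10, 89327894 to 89340971, was at 157 ± 5.17 CPM in C and 271 ± 3.14 CPM in K (log2 fold change -0.78, SE 0.035, adjusted p = 0.00144). DDX60, an antiviral helicase, had a log2 fold change of -0.87 (SE 0.074, adjusted p = 0.00360). The list passed camera with an adjusted p of 4.39e-10, and had an adjusted p of 0.0538 with an estimated correlation. Luminal epithelial markers, a list for another cell type, were also lower in C: of 8 tested, 3 fell and 0 rose, the same counts as when adjusted over the list alone (camera adjusted p = 0.0431, adjusted p = 0.282 with an estimated correlation). ELF3 (1.19 ± 0.323 CPM in C, 3.64 ± 0.305 CPM in K), SPDEF (log2 fold change -1.39, adjusted p = 0.0192) and GATA3 (-0.47, adjusted p = 0.0493) are transcription factors of luminal cells expressed at low levels here. The GATA3 call was lost whichever library was left out (adjusted p up to 0.147), the ELF3 call without C1, C3, K1 or K3, and the SPDEF call without C2, C3, K1 or K3 (both up to 0.076). KRT8, the most abundant member, was at 262 ± 19.1 CPM in C and 275 ± 19.6 CPM in K and did not pass (adjusted p = 0.553). The luminal list call was lost without C3, K1 or K2. It was also lost with limma on log2(TPM + 1) (median -0.18 against -0.34 in the main fit, adjusted p = 0.0741). That fit leaves out genes under a mean TPM of 1, ELF3 among them, and its added 1 shrinks changes at low TPM. Its medians, here and for interferon-stimulated genes, are thus on another scale and need not cover the same members.

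**Figure D2:**
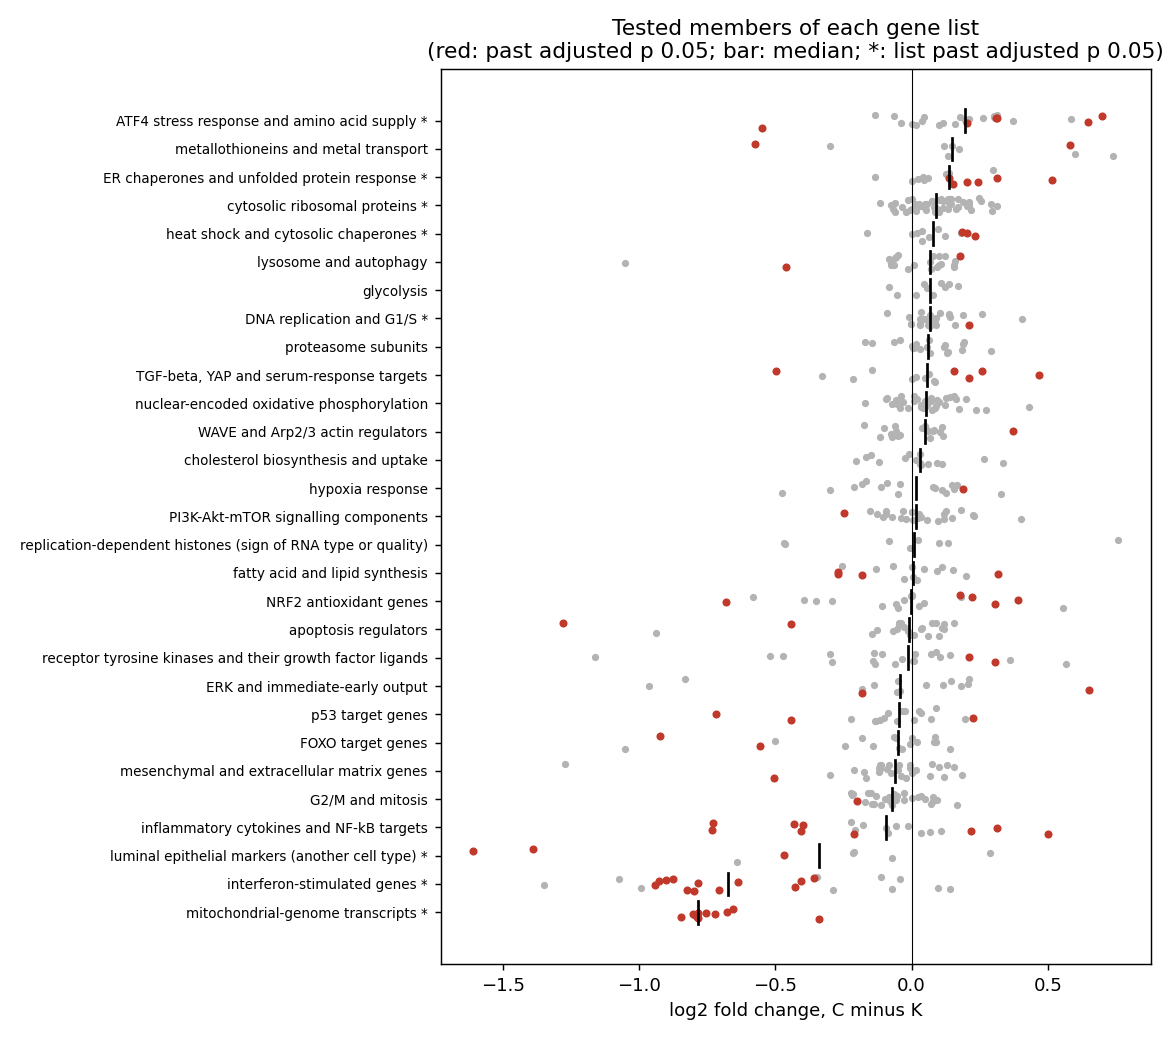
Log2 fold change of C minus K for the tested members of 29 gene lists, with members past an adjusted p of 0.05 in red, list medians as bars and an asterisk on the 8 lists past the camera threshold. The 11 mitochondrial-genome transcripts all lie below 0, around a median of -0.78.

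Genes of the ATF4 stress response, which supplies amino acids when they are short, were higher in C as a list (median 0.20, camera adjusted p = 0.000110, adjusted p = 0.119 with an estimated correlation). Of 25 tested members, 5 rose and 1 fell; adjusted over the list alone, 10 rose and 1 fell. ASNS (chromosome 7, 97852118 to 97872542), which makes asparagine, rose from 27.1 ± 0.593 CPM in K to 44.0 ± 0.966 CPM in C (log2 fold change 0.70, SE 0.046, adjusted p = 0.00181), and shares 38.6% of its windows with an overlapping gene model. PHGDH, the entry enzyme of serine synthesis, rose by a log2 fold change of 0.31 (SE 0.051, adjusted p = 0.0287). DDIT4, an inhibitor of mTOR signalling, fell against the direction of its list (log2 fold change -0.55, SE 0.073, adjusted p = 0.0175). The PHGDH call was lost when any library except K2 was left out, and the DDIT4 call without C1, C2, C3 or K3 (adjusted p up to 0.107 and 0.075).

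Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response rose as a list (median 0.14, camera adjusted p = 0.000361, adjusted p = 0.119 with an estimated correlation). Of 15 tested members, 6 rose and 0 fell, and 8 rose when adjusted over the list alone. HSPA5 (chromosome 9, 125234853 to 125241330), the main chaperone of that compartment, was at 1375 ± 20.9 CPM in C and 1106 ± 12.02 CPM in K (log2 fold change 0.31, SE 0.025, adjusted p = 0.00287). PDIA4 (log2 fold change 0.15, adjusted p = 0.0261), SELENOS (0.24, adjusted p = 0.0299) and SDF2L1 (0.52, adjusted p = 0.0314) also rose, but these 3 calls were lost when any library except K2 was left out (adjusted p up to 0.1098). Heat shock and cytosolic chaperones rose as a list (median 0.08, camera adjusted p = 0.00659, adjusted p = 0.282 with an estimated correlation), with 3 of 12 members higher and 0 lower, and 5 higher adjusted over the list alone; without K2 the call was lost. They were HSPA1A (log2 fold change 0.20, adjusted p = 0.0175), HSPA1B (0.23, adjusted p = 0.00893) and HSP90AB1 (0.19, adjusted p = 0.0324). HSPA1A and HSPA1B share 69.3% and 73.2% of their windows with other genes, mostly each other, and are uncertain as separate genes. The calls of HSPA1A and HSP90AB1 were lost when any library except K2 was left out, and that of HSPA1B without C1 or K3 (adjusted p up to 0.117).

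Cytosolic ribosomal proteins (median 0.09, camera adjusted p = 0.000515, adjusted p = 0.637 with an estimated correlation) and genes of DNA replication and G1/S (median 0.07, camera adjusted p = 0.000515, adjusted p = 0.219 with an estimated correlation) were higher in C as lists by small amounts. Of 51 ribosomal protein genes 0 passed alone, over all genes or over the list alone, and the list did not pass fry (adjusted p = 0.152). Among 28 replication genes 1 passed, with either adjustment: E2F1, a transcription factor of S-phase entry, with a log2 fold change of 0.21 (SE 0.037, adjusted p = 0.0316), lost when any library except K2 was left out (adjusted p up to 0.113). Fold changes also varied with GC content across genes, with a Spearman correlation of 0.25 over 9048 genes, which are not independent replicates. With the GC and length offset, added after the data were seen, the ribosomal protein and replication lists stayed past the camera threshold at the preset correlation.

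Components of PI3K-Akt-mTOR signalling, the pathway in the series title, did not pass as a list (median 0.02, camera adjusted p = 0.558, fry adjusted p = 0.642). RNA levels of these components do not measure the activity of the pathway. Of 26 tested members, 1 fell and 0 rose; adjusted over the list alone, 1 fell and 2 rose. PIK3CA (chromosome 3, 179148114 to 179240093), a catalytic subunit of PI3K, was at 75.4 ± 3.40 CPM in C and 89.5 ± 1.80 CPM in K (log2 fold change -0.25, SE 0.044, adjusted p = 0.0343). Its call was lost when any library except K2 was left out (adjusted p up to 0.126), with limma on log2(TPM + 1) (-0.11, adjusted p = 0.538) and with the GC and length offset added after the data were seen (-0.12, adjusted p = 0.0839). PDPK1, named after its values were seen, had counts that differed within each letter, at 1747, 3765 and 3816 reads in C1 to C3 and 3088, 3457 and 606 reads in K1 to K3. FOXO target genes, which Akt represses through FOXO factors, did not pass camera (median -0.05, adjusted p = 0.178, 0.430 with an estimated correlation). They passed fry, lower in C (adjusted p = 0.00837). In all, 11 lists passed fry but not camera, so this was not particular to FOXO targets. Of 18 FOXO targets tested, 2 fell and 0 rose, and 4 fell adjusted over the list alone. FBXO32, a ubiquitin ligase of muscle wasting, fell by a log2 fold change of -0.56 (SE 0.057, adjusted p = 0.00763). ABI2 was not analysed here; of 21 tested genes in a list of WAVE and Arp2/3 actin regulators 1 rose, with either adjustment, CYFIP2 (log2 fold change 0.37, adjusted p = 0.0299), lost when any library except C2 was left out (adjusted p up to 0.113).

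**Figure D3:**
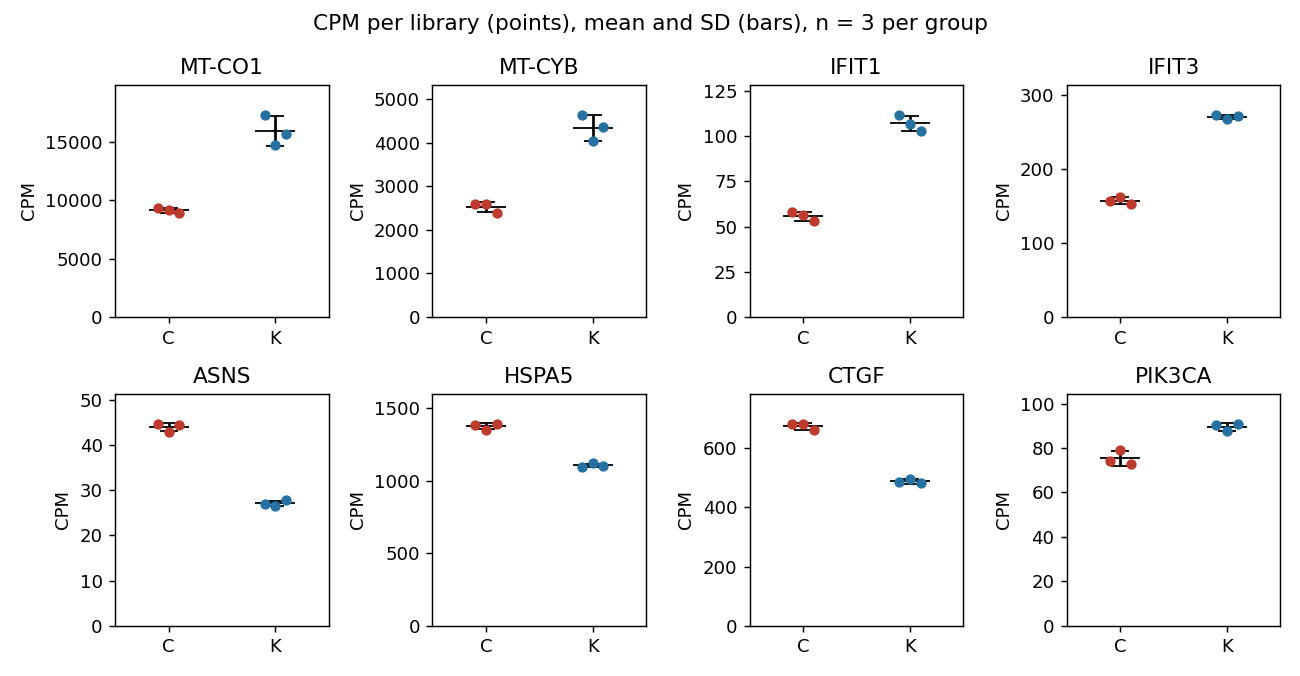
CPM per library for 8 named genes, with points for libraries and bars for the mean and SD of 3 libraries per letter; each axis starts at 0. C and K libraries do not overlap in any panel; PIK3CA has the smallest fold change of the 8.

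The other lists did not pass camera, and 21 of 29 tested lists had adjusted p between 0.0740 and 0.864. Inflammatory cytokines and NF-kB targets held 3 members that rose and 6 that fell of 19 tested (3 and 8 adjusted over the list alone), with CSF1, a macrophage growth factor, at a log2 fold change of -0.73 (SE 0.051, adjusted p = 0.00219). TGF-beta, YAP and serum-response targets had 4 rises and 1 fall of 14 (5 and 2 adjusted over the list alone). CTGF, a matrix-associated protein, was at 674 ± 11.8 CPM in C and 488 ± 7.88 CPM in K (log2 fold change 0.47, adjusted p = 0.00165). NRF2 antioxidant genes had 4 rises and 1 fall of 20 (5 and 2 over the list alone), with the smallest adjusted p at TXNRD1 (log2 fold change 0.31, adjusted p = 0.00763). Metallothioneins and metal transport had 1 rise and 1 fall of 9 (4 and 2 over the list alone), with MT1E, of a multigene family, at a log2 fold change of 0.58 (adjusted p = 0.00171). Receptor tyrosine kinases and ligands had 2 rises of 22 (3 over the list alone), among them HBEGF (0.31, adjusted p = 0.00596). Fatty acid and lipid synthesis had 1 rise and 3 falls of 16 (2 and 4 over the list alone), with SREBF1 at -0.27 (adjusted p = 0.0226), lost when any library except K2 was left out (adjusted p up to 0.0944).

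The p53 targets had 1 rise and 2 falls of 18, with either adjustment, with GDF15 at a log2 fold change of -0.72 (adjusted p = 0.00412). Apoptosis regulators had 2 falls of 24, with either adjustment, among them PMAIP1 (-0.44, adjusted p = 0.00887; 0.0529 without C1). Lysosome and autophagy genes had 1 rise and 1 fall of 23, with either adjustment, the fall being CTSD (-0.46, adjusted p = 0.00582), which shares 34.3% of its windows. Mesenchymal and matrix genes had 1 fall of 30, with either adjustment, COL5A1 (-0.51, adjusted p = 0.00693). ERK and immediate-early genes had 1 rise and 1 fall of 15 (2 and 1 over the list alone), the fall being DUSP4 (-0.18, adjusted p = 0.0270). G2/M and mitosis genes had 1 fall of 31, with either adjustment, DLGAP5 (-0.20, adjusted p = 0.0298). Hypoxia genes had 1 rise of 18 (6 and 2 over the list alone), NDRG1 (0.19, adjusted p = 0.0457), lost whichever library was left out (adjusted p up to 0.148) and at 0.11 with limma on log2(TPM + 1). The DLGAP5 call was lost when any library except K2 was left out, and the DUSP4 call without C1, C2, K1 or K3 (adjusted p up to 0.114 and 0.111). In cholesterol synthesis and uptake 0 of 16 passed, in glycolysis 0 of 10, among proteasome subunits 0 of 20 and among replication-dependent histones 0 of 8, with either adjustment. Median, mean and test differed in sign for 7 lists, namely receptor tyrosine kinases, fatty acid synthesis, NRF2, hypoxia, lysosome, ERK and histones.

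Of the lists for other cell types, 3 had under 5 tested members and were not tested as lists: keratinocyte and basal epithelial, blood cell and fibroblast markers, with 0 of 2, 0 of 3 and 0 of 3 past the threshold. Their most abundant members were SFN at 131 ± 5.50 CPM in C and 129 ± 6.61 CPM in K, SRGN at 365 ± 8.89 and 379 ± 3.25 CPM, and COL1A1 at 8.15 ± 0.717 and 8.64 ± 0.159 CPM. HIST1H2BK, the most abundant histone, was at 158 ± 1.36 CPM in C and 159 ± 3.87 CPM in K (adjusted p = 0.930). It shares 50.5% of its windows with other genes, so its count is uncertain. Nuclear-retained RNAs were not analysed here.

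Among further large rises were SLC25A24, a mitochondrial carrier (log2 fold change 0.58, adjusted p = 0.00165), IRAK1, a kinase of interleukin-1 signalling (0.47, adjusted p = 0.0423), HCFC1, a chromatin cofactor (0.43, adjusted p = 0.0314), and CCP110, a centriole protein (0.41, adjusted p = 0.0429). The calls of HCFC1 and CCP110 were lost when any library except K2 was left out, and that of IRAK1 when any library except K3 was left out (adjusted p up to 0.130). Over all alternatives CCP110 fell to 0.27 (adjusted p up to 0.151) and IRAK1 to 0.32 (adjusted p up to 0.144). Of the 46 named genes called, 31 lost the call with the replicate block. With limma on log2(TPM + 1) 9 lost it, namely CCP110, DUSP4, GATA3, HCFC1, HLA-C, IRAK1, NDRG1, PIK3CA and SREBF1, and DLGAP5 changed sign. With the GC and length offset 5 lost it, namely DLGAP5, IRAK1, NDRG1, PDIA4 and PIK3CA. Of the 2 genes at least 2-fold higher in C, chosen after their values were seen, EFR3B had a log2 fold change of 1.17 (SE 0.13, adjusted p = 0.0104). The other, AP001781.3, had 0 reads in K and was at least 103-fold higher in C against a floor of 3 reads over the group, but shares 93.8% of its windows with other gene models. COL7A1, a collagen of anchoring fibrils also chosen after its values were seen, was at 12.8 ± 0.617 CPM in C and 34.4 ± 2.37 CPM in K (log2 fold change -1.43, SE 0.074, adjusted p = 0.00144). Of the 26 genes changed at least 2-fold, 8 overlap another gene's exons on the same strand and 3 share at least 50% of their windows. Of the 51 named genes, 9 overlap another gene on the same strand (ELF3, MT-ND4, MT-ND4L, MT-ATP6, CTSD, IRAK1, HSPA1B, ASNS and HLA-C) and 9 on the opposite strand (ELF3, DDIT4, CTSD, SREBF1, PIK3CA, KRT8, CYFIP2, CTGF and SLC25A24), so their counts are less certain.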

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

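The 2 settings without mitochondrial-genome genes and with a GC and length offset were chosen after seeing the data. The 508 main calls kept their sign in every setting where they were tested except limma on log2(TPM + 1), where 5 of 488 had the opposite sign and 0 of these 5 passed the threshold. Counts of genes past the threshold outside 1.5 times the main 508 were 1039 with DESeq2, 279 with limma on log2(TPM + 1) and 25 with the replicate block. Leaving out 1 library gave 533 without K2, 326 of them among the main 508, and 77 to 117 without any other. Every such fit has the same residual degrees of freedom, fewer than the main fit, so these cannot explain that gap. Why leaving out K2 differed was not tested. The 26 genes at 2-fold became 6 with TPM and 3 with the block, and 9 to 26 with 1 library left out. The cause of the DESeq2 and TPM differences was not tested. Library numbers did not pair the letters: the correlations of deviations for C1 with K1, C2 with K2 and C3 with K3 were -0.089, 0.032 and -0.0043, and not every library correlated best with its own number. The 8 lists called became 0 with an estimated correlation and 18 with fry, which asks another question and called 7 of the 8 but not ribosomal proteins (adjusted p = 0.152), and were 7 to 9 with 1 library left out. Of 51 named genes, 46 were called, and 23 of these stayed past the threshold whichever library was left out. DLGAP5 had a log2 fold change of 0.0847 with TPM (adjusted p = 0.607), opposite to its main value, and the cause was not tested. Over all its alternatives that adjusted p ran from 0.000726 to 0.607. Of 808 values for named genes under the alternatives, 652 kept their side and direction and 155 lost the call. Without mitochondrial-genome genes their own values cannot be had, and ELF3 lay under the TPM filter. In simulation 24% of the changed genes, drawn at or above the median expression, were recovered at the smallest fold tried. Other depths and numbers of libraries were not simulated.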

Other observations

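The tests of reads shared with nuclear copies, of yield in library preparation, of gene counts that jump between libraries and of other splits were chosen only after the result was seen, as were the GC and length offset and the 3 lists of the next paragraph.

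After the calls were seen, 3 further gene lists were written from textbook knowledge, so they are not independent evidence. Their adjusted p below are over all 32 lists, planned and added, and none passed with an estimated correlation. Their members named here were chosen after their values were seen. Class I antigen presentation and interferon-gamma genes were lower in C (median -0.47, camera adjusted p = 7.23e-05, adjusted p = 0.0986 with an estimated correlation), with 8 of 23 tested members lower and 1 higher. Those lower included NLRC5, a regulator of class I genes (log2 fold change -0.47, SE 0.034), AIM2, a DNA sensor (-0.84, SE 0.10), and GBP2 (-0.74, SE 0.13), while HLA-C was the 1 that rose. Complement and acute-phase genes were lower (median -0.39, camera adjusted p = 0.00485, adjusted p = 0.152 with an estimated correlation), with 5 of 13 lower and 1 higher. Those that fell included C3, SAA1 (-0.78, SE 0.10), C1S (-1.06, SE 0.17) and CFB (-0.53, SE 0.10), and PTX3 rose (0.35, SE 0.057). Ribosome biogenesis factors were higher (median 0.07, camera adjusted p = 0.00485, adjusted p = 0.152 with an estimated correlation), with 10 of 71 higher and 1 lower, KRR1. Within the inflammatory list, also read after the values were seen, the 6 falls included IL6 (-0.73, SE 0.10), IL1B (-0.41, SE 0.033) and BCL3 (-0.40, SE 0.079). The 3 rises were RELB (0.50, SE 0.054), NFKB2 (0.32, SE 0.053) and NFKB1 (0.22, SE 0.036).

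The 11 mitochondrial-genome transcripts were lower in C. Under 3 other scalings their median nearest 0 was -0.76, but the all-gene median stayed between -0.00477 and 0.0166. These scalings thus shifted too little to test scaling. TMM itself holds the main all-gene median (-0.00445) near 0, so only its gap to -0.78 for these transcripts bears on scaling. Scaling of a library moves all its genes alike and would not make such a gap, which argues against scaling as its source. A GC and length trend is argued against by a median of -0.76 after the offset. Reads shared with nuclear copies are argued against by the 5 transcripts with under 1% shared windows, whose median was -0.79, although MT-ND3 among them was at -0.34. A lower yield of mitochondrial RNA in library preparation cannot be told apart from a lower amount in the cells, since all 11 were lower and both predict that. The difference between the study's arms stays open as well, and which letter was treated is not known.

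Interferon-stimulated genes were lower in C, with a list call that was lost with an estimated correlation (adjusted p = 0.0538). Their median was -0.39 with limma on log2(TPM + 1), which shrinks changes at low TPM. A GC and length trend is argued against by a median of -0.65 after the offset, with the list past its threshold at the preset correlation. One library as the source is argued against, since the median nearest 0 over the 6 fits that leave out a library was -0.52. Other differences between the cultures, which the labels do not describe, and the treatment itself remain open.

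Some gene counts jumped between libraries of one letter: of 6902 genes with a mean of at least 10 CPM, 85 differed by over 1.5 log2 units within a letter. That limit was chosen after the widest genes, many of them readthrough models, had been listed. Same-strand exon overlaps were 2.65 times as frequent among the 85 as among other abundant genes (43.5% against 16.4%, two-sided Fisher's exact p = 5.09e-09), but 1.98 times at a limit of 1, under the 2 times set for this test, and 3.83 and 5.40 times at limits of 2 and 3. Reads divided differently between overlapping gene models may explain part of the jumps, though 37 of the 85 have such an overlap and the others do not. The gene length implied by counts and TPM had a median range of 0.302 log2 units in the 85 and 0.0698 in the others. That was a median of 0.164 of the gene's own jump (quartiles 0.0587 and 0.326) and under 0.5 of it in 70 of 85, which argues against transcript models of another length as the whole cause. Sums over the genes sharing their windows left 3 genes at least 2-fold changed, named after their values were seen, undecided. At MINOS1-NBL1 the sum was 119 ± 35.0 CPM in C and 120 ± 5.04 CPM in K (log2 ratio -0.0115), an SD beyond the 19.2 CPM that would separate moved reads from a change of that gene alone. At AP001781.3 (log2 ratio 0.0383) its own 3.14 CPM is too small a part of the sum to move it beyond its spread. At AC011511.1 the sum gave -4.04 without its main sharing gene, which was not used here.

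The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 508 called genes and the highest other 5, with 1 of 10 splits as large. For 2-fold genes these were 26 and 3, with 1 split as large, and for lists called 8 and 5, again with 1 split as large.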
